A study of Mus musculus with 12 samples.

How the data were processed

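H3K27me3, the trimethylation of lysine 27 of histone H3 that Polycomb complexes place on repressed chromatin, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in epithelial cells of the mouse small intestine. Per the labels, 4 populations were sorted by flow cytometry: EpCAM-positive epithelium of embryos at embryonic day 12.5 (E12.5) and embryonic day 14.5 (E14.5), Lgr5-positive intestinal stem cells (ISC) and enterocytes (AE), the last 2 populations from adult males at postnatal day 60. CD31- and CD45-positive cells were gated out, and chromatin was sheared to fragments of about 350 to 700 bp. Each population gave 2 ChIP libraries, described in the series design as biological duplicates, and 1 input library. The 8 ChIP libraries were analysed here as 4 groups of 2. The 4 inputs enter only through the control columns of the lists.

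Each ChIP library came as 1 deposited list of enriched islands. Per the submitters' processing notes, the tools were bcl2fastq 1.8.4, Bowtie 1.1.2, SAMtools 1.2 and SICER 1.1, and the genome build was mm9. SICER merges neighbouring enriched windows into islands, which suits broad marks such as H3K27me3. The lists carry no header. Their columns were read from the values as chromosome, start, end, ChIP reads, control reads, p-value, fold over control and false discovery rate (FDR). All island borders fall on a grid of 200 bp windows, and no FDR exceeds 0.01. Island read counts are whole numbers as deposited, not normalized. The fold is the authors' ratio of ChIP to control reads after scaling by library size, and within each list ChIP reads divided by control reads and by fold gave 1 constant. The p-value and FDR of each island are likewise the authors' own. Islands were called separately for each replicate. In intervals that both replicates of a group share exactly (30 in E12.5, 52 in E14.5, 17 in ISC and 41 in AE), the control counts were identical in all cases, so both replicates were called against the same control. The ChIP counts in these intervals differed in all but 1 of the E14.5 intervals, so no library was counted as a copy of another.

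The reads of a library are listed only inside its own islands, so no count test across libraries could be run, and the total number of reads per library is unknown. The constant of each list gives the size of the ChIP library relative to its control, and since replicates share a control, their relative sizes: replicate 1 was 0.928 times replicate 2 in E12.5, 1.63 times in E14.5, 1.09 times in ISC and 1.68 times in AE. Between groups the controls differ, so relative depth is unknown there. The ChIP reads inside islands numbered between 1171968 and 6627853 per library. A position outside the islands of a library was not called there, which does not exclude a lower level of the mark. The authors' fold was used only to describe or filter islands within a list. A fold given for a stretch is that of the longest island over it in the list, which can reach beyond the stretch.

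Every list was painted on the 200 bp grid with Python 3.11.15 and numpy 2.4.6. Coordinates are given 1-based on mm9. Agreement of 2 libraries was the Jaccard index, the length covered in both divided by the length covered in either. The mean index of same-group pairs minus that of different-group pairs was tested by an exact two-sided permutation test over the 105 ways of forming 4 pairs from 8 libraries. Embryonic (E12.5 and E14.5) against adult (ISC and AE) libraries were tested in the same way over 35 splits. These splits move single libraries, so replicates of a population count as separate units. Likeness of replicates therefore also favours the real split, and p-values of embryonic against adult tests do not extend to populations. For each developmental step, a stretch was gained when both libraries of the later group and neither of the earlier group covered it, and lost in the opposite case. With 2 libraries against 2 there are 3 splits, so no p-value below 0.333 can be had, and the gained plus lost length is set beside that of the 2 other splits, each of which groups 1 library of either population. For embryonic against adult, length covered in 4 of 4 libraries of one kind and in 0 of 4 of the other was set beside the 34 other splits.

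The design fixed before the data were examined counted gene promoters and tested gene lists. The lists hold no gene names, and the gene table at hand belongs to another mouse assembly, so promoters and gene lists were not analysed here. As that design foresaw for this case, lengths replaced promoter counts, and the regions named are the 8 longest stretches gained and the 8 longest lost at each step, by coordinate. The same rule of the 8 longest was applied to embryonic alone, adult alone and all 8 libraries. Whether a named region lies in a gene is not given. Promoter windows, gene sets and the gene lists, with their alternatives, were therefore not run.

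Alternatives planned beforehand were islands with a fold of 3 or more, islands with an FDR of 1e-10 or less, equal covered length, chromosomes without X and Y, each replicate left out in turn, the share of islands covered by at least 50% in place of the Jaccard index, and the replicate number as a block. For equal covered length, the islands with the smallest p-value were taken from each list until they covered the length of the shortest list. Alternatives added after seeing the data were a fold of 1.5 or more, equal covered length with each replicate left out, and removal of islands whose control reads per kb exceeded 3 times the median of their list. The share of covered length on chromosome X was also chosen after seeing the data.

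The code was tested on simulated data. From the 9940 islands of E14.5 replicate 2, 2 against 2 lists were made in which 200 islands were gained and 200 lost. All of the gained and lost length was recovered without dropout. With 10% of islands dropped at random from each list, 78.6% of the gained and 84.8% of the lost length was recovered, and with 30% dropped 47.3% and 52.0%. The 30% case also gave 4.54 Mb of false gains beside 2.47 Mb of true gains. Requiring both replicates against neither therefore misses changes and counts dropout as change where lists are incomplete. The simulated lists come from 1 common list and keep its island borders. Dropout in the real lists was not estimated and may be higher, since the real duplicates had Jaccard indices of 0.198 to 0.447. Versions of the other tools were scipy 1.17.1 and matplotlib 3.10.9.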

Results

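H3K27me3 islands were compared across 4 populations of mouse small-intestinal epithelium: embryonic epithelium at E12.5 and E14.5, adult Lgr5-positive stem cells (ISC, the dividing cells of the crypt base) and adult enterocytes (AE, the absorptive cells of the villus). The series title names the specification of adult stem cells and their differentiation as its subject, so the comparisons follow E12.5 to E14.5, E14.5 to ISC and ISC to AE, and embryonic against adult. The E12.5 lists covered 62.5 and 76.0 Mb, the E14.5 lists 75.9 and 109 Mb, the ISC lists 241 and 60.8 Mb, and the AE lists 80.0 and 91.0 Mb. Embryonic libraries covered 80.9 ± 19.8 Mb (SD, n = 4) and adult libraries 118 ± 82.9 Mb (SD, n = 4), with an exact permutation p of 0.600. Median island lengths ran from 4.6 kb in E12.5 replicate 2 to 10.4 kb in ISC replicate 1, and median folds over control, which are the authors' own values, from 1.38 in E12.5 replicate 1 to 1.67 in E14.5 replicate 2. ChIP reads inside islands, which depend on how much was called, numbered 1171968 and 2114128 for E12.5, 3020599 and 2999884 for E14.5, 6627853 and 1493464 for ISC, and 3124099 and 2427692 for AE. The size of the whole ChIP library of replicate 1 relative to replicate 2, from the control they share, was 0.928 for E12.5, 1.63 for E14.5, 1.09 for ISC and 1.68 for AE. The extent of calling differed by up to 3.97 times between replicates of a group (ISC), and comparisons at equal covered length are given beside those of the full lists.

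**Figure D1:**
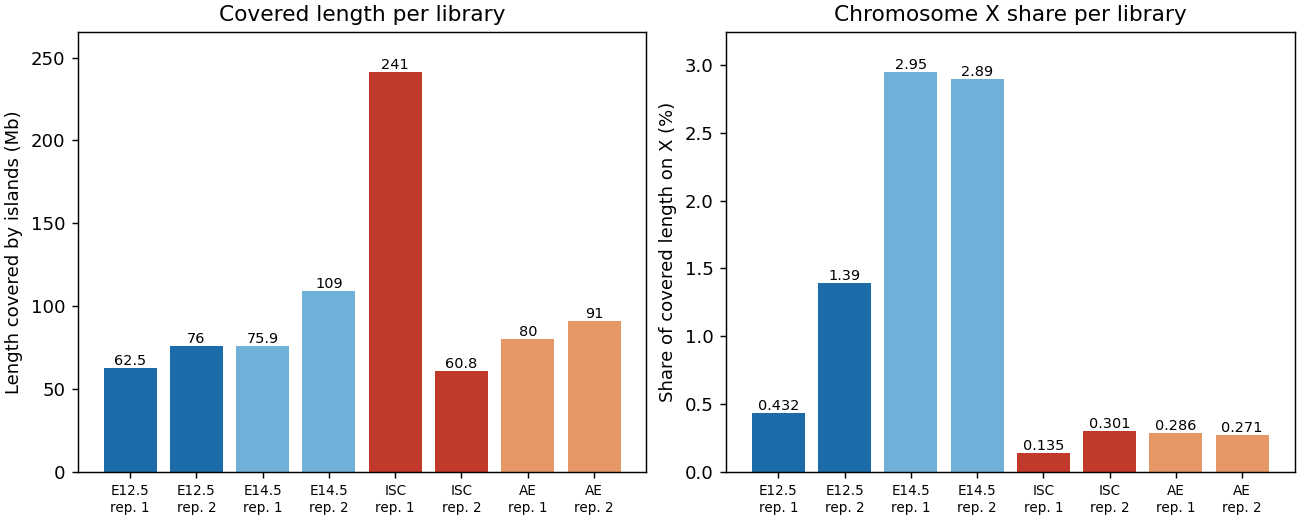
Length covered by H3K27me3 islands in Mb (left) and share of that length on chromosome X in percent (right), 1 bar per library. ISC replicate 1 covered 241 Mb against 60.8 to 109 Mb in the other libraries, and the X share lay between 0.432% and 2.95% in embryonic and between 0.135% and 0.301% in adult libraries.

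A core of 11.0 Mb was covered in all 8 libraries, in embryo and adult, stem cell and enterocyte alike. Its longest stretches were 68.0 kb on chromosome 15 (102775601 to 102843600), 56.6 kb on chromosome 11 (96111201 to 96167800), 50.0 kb on chromosome 6 (52154801 to 52204800) and 45.8 kb on chromosome 4 (115594001 to 115639800). The next were 35.6 kb on chromosome 2 (105498601 to 105534200), 34.8 kb on chromosome 3 (99036201 to 99071000), 34 kb on chromosome 1 (78184201 to 78218200) and 33.8 kb on chromosome 6 (83641401 to 83675200). The chromosome 15 stretch lay in islands with folds of 2.01 and 4.67 at E12.5, 3.85 and 5.37 at E14.5, 4.03 and 2.32 in ISC, and 2.36 and 2.43 in AE. Islands over the core had the higher median fold in each of the 8 lists, from 1.48 against 1.43 for the remaining islands in AE replicate 1 to 2.79 against 1.60 in E14.5 replicate 2. They were also longer, for example 10.6 against 8.6 kb (medians) in E12.5 replicate 1 and 25.6 against 10.0 kb in ISC replicate 1. Long islands overlap the core more easily, so part of this difference follows from the classing. The core was 2.96% of all length called anywhere, and 54.9% of that length was called in a single library.

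With the islands as deposited, the E14.5 replicates and the AE replicates had the highest indices of all pairs, whereas the E12.5 replicates had a lower index than E12.5 with E14.5 pairs on average, and the ISC replicates a lower one than ISC with AE pairs. The Jaccard index was 0.447 between the E14.5 replicates and 0.346 between the AE replicates, against 0.202 for E12.5 and 0.198 for ISC. The ISC index is held down by the unequal length of the lists, and at equal covered length the ISC replicates reached 0.338. With the islands as deposited, ISC replicate 2 and AE replicate 1 had an index of 0.308, and ISC replicate 1 and AE replicate 2 one of 0.271. At equal covered length the 4 pairs of ISC with AE libraries ranged from 0.314 to 0.386, beside 0.381 between the AE replicates and 0.552 between the E14.5 replicates. E12.5 replicate 2 was closest to E14.5 replicate 1, at 0.337, and pairs of E12.5 with E14.5 libraries averaged 0.261 (0.304 at equal covered length, against 0.219 between the E12.5 replicates). The mean over same-group pairs was 0.298 ± 0.121 (SD, 4 pairs) and over different-group pairs 0.225 ± 0.0568 (SD, 24 pairs), a difference of 0.0729 that 2 of all possible pairings of the libraries reached, the real one included (exact permutation test, two-sided p = 0.0190). The other pairing, which reached 0.0832, kept the E12.5 and E14.5 pairs and joined each ISC library to an AE library; at equal covered length no other pairing reached the real difference of 0.106 (exact permutation p = 0.00952). The call rests on the E14.5 and AE duplicates: without E14.5 replicate 1 or 2 the difference was 0.0297 or 0.0307 (exact permutation p = 0.362 and 0.381), and without AE replicate 1 or 2 it was 0.0588 or 0.0598 (exact permutation p = 0.0762 for each). It was also lost among islands with an FDR of 1e-10 or less, at a difference of 0.0758 (exact permutation p = 0.0762).

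**Figure D2:**
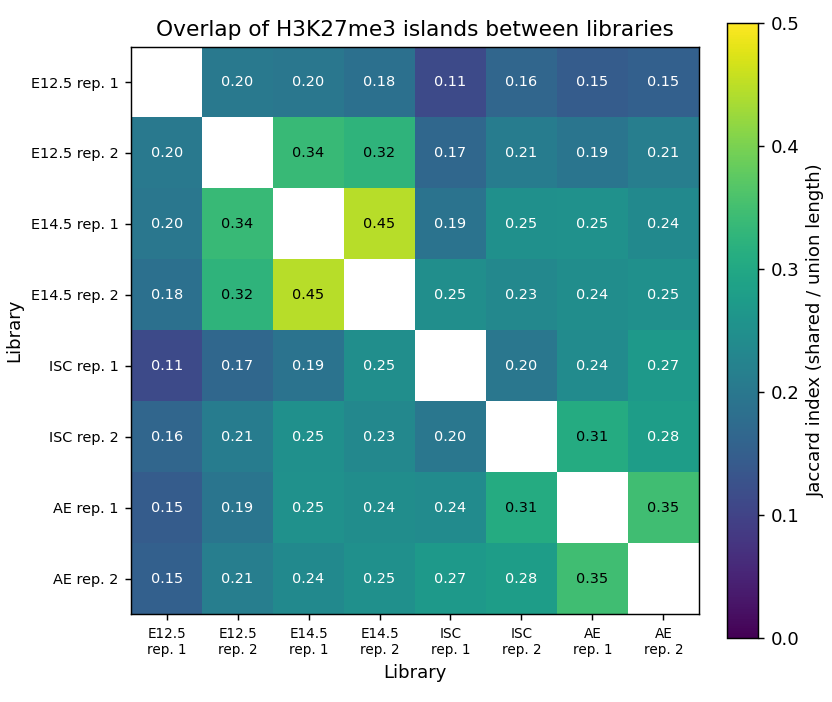
Jaccard index (shared length divided by union length) for each pair of the 8 libraries, with replicates of a population next to each other. The pair of E14.5 libraries had the highest index, 0.447, and E12.5 replicate 1 with ISC replicate 1 the lowest, 0.112.

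On average, libraries of one kind, embryonic or adult, shared more length with each other than with libraries of the other kind. Single pairs did not all follow. E14.5 replicate 2 had an index of 0.325 with E12.5 replicate 2 and 0.184 with E12.5 replicate 1, against 0.234 to 0.251 with the adult libraries. Pairs within the embryonic or within the adult libraries had a mean index of 0.278 ± 0.0790 (SD, 12 pairs), and embryonic with adult pairs one of 0.204 ± 0.0448 (SD, 16 pairs). No other of the 35 splits gave a difference as large as 0.0739 (exact permutation test, two-sided p = 0.0286, the smallest this design allows). Among islands with an FDR of 1e-10 or less the difference was 0.0687, and with a fold of 1.5 or more it was 0.0676 (exact permutation p = 0.0571 for each). Most of the 35 splits part replicates, whose likeness favours the real split, so these p-values hold for libraries and not for populations. With replicate pairs set aside, E12.5 with E14.5 libraries averaged 0.261 and ISC with AE libraries 0.275. Embryonic with adult populations averaged 0.163 to 0.246.

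Length covered in all embryonic and no adult library came to 1.41 Mb in 434 stretches, and length covered in all adult and no embryonic library to 4.45 Mb in 1288 stretches. The longest embryonic stretch was 23.4 kb on chromosome 8 (112576001 to 112599400), where the islands had folds of 1.43 and 2.58 at E12.5 and 2.54 and 2.47 at E14.5. A second stretch on chromosome 8 (87284201 to 87305200, 21.0 kb) lay in longer islands of 31.4, 57.2, 58 and 68.8 kb. Their folds were 1.75, 3.36, 2.38 and 3.01 in the same order of libraries. Adult islands began just after its end, from 87305201 in ISC replicate 1 to 87307801 in AE replicate 1, so it flanks length that adult libraries also called. The other embryonic stretches were on chromosome 2 (26391401 to 26411200), chromosome 8 (108262001 to 108280800), chromosome 1 (122859401 to 122877000, 137805401 to 137822200 and 122842201 to 122858000) and chromosome 11 (116978201 to 116993200). The longest adult stretch was 31.6 kb on chromosome 7 (52918001 to 52949600), with folds of 2.92 and 1.53 in ISC and 1.87 and 1.99 in AE. It was followed by 28.8 kb on chromosome 15 (100604001 to 100632800), with folds of 1.74 and 1.203 in ISC and 1.38 and 1.52 in AE. The others were on chromosome 9 (42739001 to 42766000 and 110630601 to 110656200), chromosome 5 (125745001 to 125770800 and 125778201 to 125803000) and chromosome 8 (12687801 to 12712000 and 12023601 to 12044400). The total of 5.86 Mb was the highest of the 35 splits, the next being 2.92 Mb. At equal covered length the totals were 2.16 Mb embryonic and 3.11 Mb adult, 5.27 Mb against 0.766 Mb for the next split. The real split was not the highest among islands with an FDR of 1e-10 or less (1.69 against 4.15 Mb) or a fold of 1.5 or more (2.10 against 4.01 Mb). Both times the split that gave most set E12.5 replicate 1, ISC replicate 2 and both AE libraries against the rest. These libraries alone held 0 Mb of its length, and the rest alone held all of it. With an FDR of 1e-10 or less, the lists of these libraries covered 9.08 to 39.9 Mb and the rest 32.8 to 134 Mb. With a fold of 1.5 or more, they covered 16.5 to 41.0 Mb and the rest 47.1 to 119 Mb. Nor was the real split the highest without E12.5 replicate 2 (6.64 against 7.38 Mb), E14.5 replicate 1 (6.73 against 7.32 Mb) or E14.5 replicate 2 (7.28 against 8.40 Mb), while at equal covered length it was the highest in each of the 8 cases with 1 library left out. The embryonic length also moved by over 1.5 times without E12.5 replicate 1 (4.80 Mb) and ISC replicate 1 (2.58 Mb), and the adult length without ISC replicate 2 (11.2 Mb), AE replicate 1 (6.74 Mb) and AE replicate 2 (6.76 Mb).

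**Figure D3:**
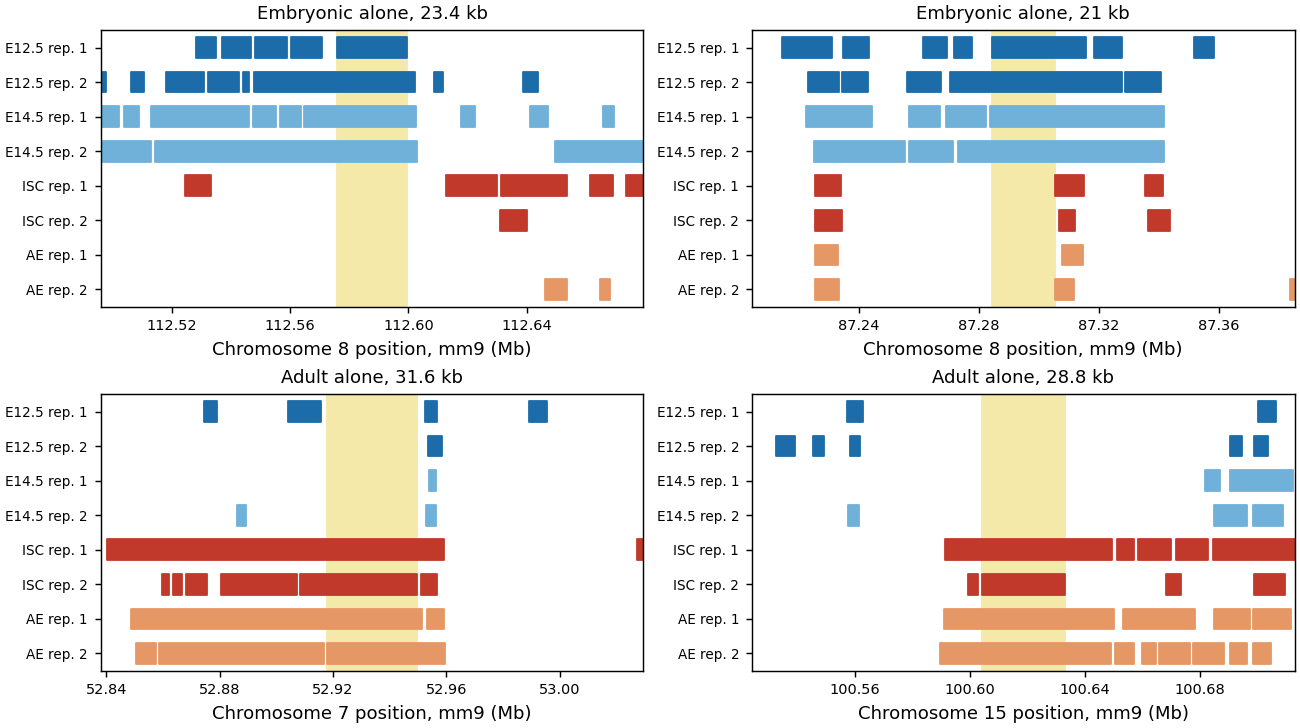
H3K27me3 islands (bars) in the 8 libraries around the 2 longest stretches called in embryonic libraries alone (top) and the 2 longest called in adult libraries alone (bottom), against mm9 position in Mb. The shaded stretches of 23.4, 21.0, 31.6 and 28.8 kb are covered in 4 of 4 libraries of one kind and in none of the other.

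From E12.5 to E14.5, 18.0 Mb were gained and 2.56 Mb lost, while 18.6 Mb were covered in all 4 libraries. Both E12.5 libraries covered 23.3 Mb and both E14.5 libraries 57.1 Mb, so less length could be lost than gained. The unequal likeness of the replicates therefore enters the excess of gains. The longest gain was 39.2 kb on chromosome 18 (60398401 to 60437600), where no E12.5 library had an island and the E14.5 islands had folds of 3.11 and 3.76. The ISC libraries covered 77% and 16% of it and the AE libraries 85% and 58%. Chromosome 15 held 4 of the 8 longest gains (12665801 to 12689200, 77565801 to 77589000, 101688201 to 101709000 and 102687601 to 102707600), the last of which ends before the 68.0 kb core stretch of that chromosome begins. In E14.5 replicate 1 a single island of 197.4 kb covered both. The remaining 3 were on chromosome 2 (148653401 to 148671800), chromosome 4 (125135201 to 125153000) and chromosome 8 (19935201 to 19953200). The chromosome 8 stretch had folds of only 1.16 and 1.15 at E14.5, with 68.1 and 64.9 control reads per kb. The longest loss, 83.2 kb on chromosome 1 (90106001 to 90189200), had folds of 1.06 and 1.04 at E12.5 and 106 control reads per kb in the list with the fewer, against 22.3 per kb over the autosomal islands of E12.5 replicate 1. The other 7 longest losses spanned 9.6 to 15.0 kb: chromosome 1 (85313601 to 85328600), chromosome 9 (61699401 to 61713000), chromosome 4 (146853801 to 146866400), chromosome 10 (80861401 to 80873000), chromosome 5 (68221601 to 68232600) and chromosome 17 (26248801 to 26259000 and 67057601 to 67067200). The gained and lost length came to 20.6 Mb, against 8.37 and 5.08 Mb in the 2 splits that mix the ages, and to 13.3 Mb against at most 4.09 Mb at equal covered length, where 10.5 Mb were gained and 2.76 Mb lost. Among islands with an FDR of 1e-10 or less the loss was 0.0618 Mb beside a gain of 13.4 Mb, and with a fold of 1.5 or more 11.5 Mb were gained and 0.370 Mb lost. A loss must be called in both E12.5 libraries, and E12.5 replicate 1 kept only 9.08 and 16.5 Mb in these settings, so no more could be lost. E12.5 replicate 2 kept 32.8 and 52.8 Mb. Requiring only the remaining library of a group, losses exceeded gains without E12.5 replicate 1 (28.3 Mb lost, 21.1 Mb gained) and nearly equalled them without E12.5 replicate 2 (34.7 Mb lost, 35.4 Mb gained). A single E12.5 library then suffices for a loss, while a gain still needs both E14.5 libraries, so this rule favours losses. Gains were 57.5 Mb and losses 2.88 Mb without E14.5 replicate 1, and 33.6 and 4.39 Mb without E14.5 replicate 2, where the rule favours gains. The excess of gains thus depends on how many libraries of each age are required.

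From E14.5 to adult stem cells, 18.0 Mb were gained and 12.48 Mb lost. The longest gain was 70.0 kb on chromosome 5 (125744801 to 125814800), with folds of 2.65 and 1.61 in ISC. The AE libraries covered 100% and 98% of it, and the E12.5 libraries 11% and 10%. The next were chromosome 7 (52908401 to 52949600, 41.2 kb, folds 2.92 and 1.53) and chromosome 2 (17945201 to 17977800, 32.6 kb, folds 4.03 and 2.27). The other 5 were on chromosome 15 (100604001 to 100632800), chromosome 8 (12021601 to 12049200 and 12684401 to 12712000) and chromosome 9 (42739001 to 42766000 and 42622001 to 42648400). All 8 were at least partly covered in both AE libraries. The longest loss was 48.2 kb on chromosome 2 (26370601 to 26418800), with folds of 1.61 and 1.76 at E14.5, and the next 41.0 kb on chromosome 8 (108249401 to 108290400), with folds of 2.05 and 2.72. The other losses were on chromosome 8 (112564801 to 112602600), chromosome 1 (122839401 to 122877000), chromosome 11 (116974801 to 117010800 and 40256001 to 40286000), chromosome 7 (131179401 to 131211400) and chromosome 3 (14890201 to 14920600). The 2 with the highest E14.5 folds were chromosome 3, with 2.81 and 3.48, and the second of those on chromosome 11, with 2.73 and 3.10. None of the 8 lost stretches touched an island in either AE library. Of all lost length, 85.9% was called in neither AE library and 2.52% in both, whereas of the gained length 28.4% was called in both AE libraries and 42.2% in neither. At equal covered length, 43.2% of the gained length was called in both AE libraries and 26.01% in neither, and of the lost length 6.12% in both and 78.1% in neither. Chromosome X carried 7.12% of the lost and 0.0222% of the gained length.

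The change at this step, 30.5 Mb, exceeded the 20.3 and 6.46 Mb of the mixed splits, and at equal covered length it was 23.5 Mb against at most 4.83 Mb. The margin narrowed to 11.9 against 11.2 Mb with an FDR of 1e-10 or less, and to 15.6 against 12.4 Mb with a fold of 1.5 or more. Which direction was longer depended on the lists. Losses exceeded gains at equal covered length (14.7 against 8.85 Mb), with an FDR of 1e-10 or less (8.63 against 3.29 Mb) and with a fold of 1.5 or more (9.99 against 5.56 Mb). A gain must be called in both ISC libraries, and ISC replicate 2 kept only 18.4 and 25.2 Mb in the last 2 settings. The E14.5 lists kept 45.0 and 63.7 Mb, then 47.1 and 74.9 Mb. With a fold of 3 or more, 2.46 Mb were lost and 0.00420 Mb gained, and only 5 islands of ISC replicate 2 passed that fold. Losses also exceeded gains without E14.5 replicate 1 (37.9 against 19.5 Mb) and without ISC replicate 1 (31.6 against 26.6 Mb). Leaving out an E14.5 library favours losses, since a single library then suffices for them, and leaving out an ISC library favours gains. Without E14.5 replicate 2 the loss was 23.7 Mb and the gain 23.9 Mb, and without ISC replicate 2 the gain rose to 165 Mb beside a loss of 13.5 Mb.

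From stem cells to enterocytes, 2.62 Mb were gained and 11.9 Mb lost. The total of 14.54 Mb lay below both mixed splits, 24.7 and 16.2 Mb. Of these, 23.9 and 15.6 Mb lay on the side of the pair with ISC replicate 1, whose list covered 241 Mb. The comparison therefore reflects that list and cannot decide whether the step exceeds replicate differences. With an FDR of 1e-10 or less the total was 2.98 Mb, against at most 9.54 Mb in a mixed split. At equal covered length the total was 9.50 Mb, with 5.47 Mb gained and 4.03 Mb lost, against at most 8.14 Mb in a mixed split. Of the 8 longest gains, 4 had no island in any of the other 6 libraries: chromosome 19 (58741201 to 58754600, folds 2.10 and 1.34), chromosome 3 (98062601 to 98075800, folds 1.45 and 1.27), chromosome 11 (58406801 to 58417400, folds 1.30 and 1.22) and chromosome 14 (66245201 to 66255600, folds 1.64 and 1.32). Embryonic libraries had islands over the other 4, on chromosome 13 (12990801 to 13007800), chromosome 4 (146769601 to 146785800), chromosome 5 (144139801 to 144151000) and chromosome 11 (58209001 to 58219400). On chromosome 11 this was E14.5 replicate 2 alone, over 30.8% of the stretch. Among the losses, the stretches on chromosome 11 (3025401 to 3100200) and chromosome 9 (3015201 to 3032800) were called in all 6 libraries other than AE, with at least 422 and 176 control reads per kb. The stretch on chromosome 8 (19960201 to 19978200) had folds of 1.1 in both ISC lists. The other 5 losses were on chromosome 9 (45373001 to 45397400), chromosome 5 (113053601 to 113077200), chromosome 16 (95759401 to 95781200), chromosome 12 (86871201 to 86889800) and chromosome 19 (6564601 to 6582800), with ISC folds between 1.15 and 1.498. Losses were 2.24 Mb and gains 0.736 Mb with an FDR of 1e-10 or less, 5.41 and 1.44 Mb with a fold of 1.5 or more, and 0.00500 and 0.0528 Mb with a fold of 3 or more. Without AE replicate 1, where a single AE library suffices for a gain, gains (18.96 Mb) exceeded losses (17.9 Mb). Losses were longer without AE replicate 2 (18.1 against 16.3 Mb), ISC replicate 1 (20.9 against 17.7 Mb) and ISC replicate 2 (149 against 3.15 Mb). Leaving out an ISC library favours losses by the same rule.

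**Figure D4:**
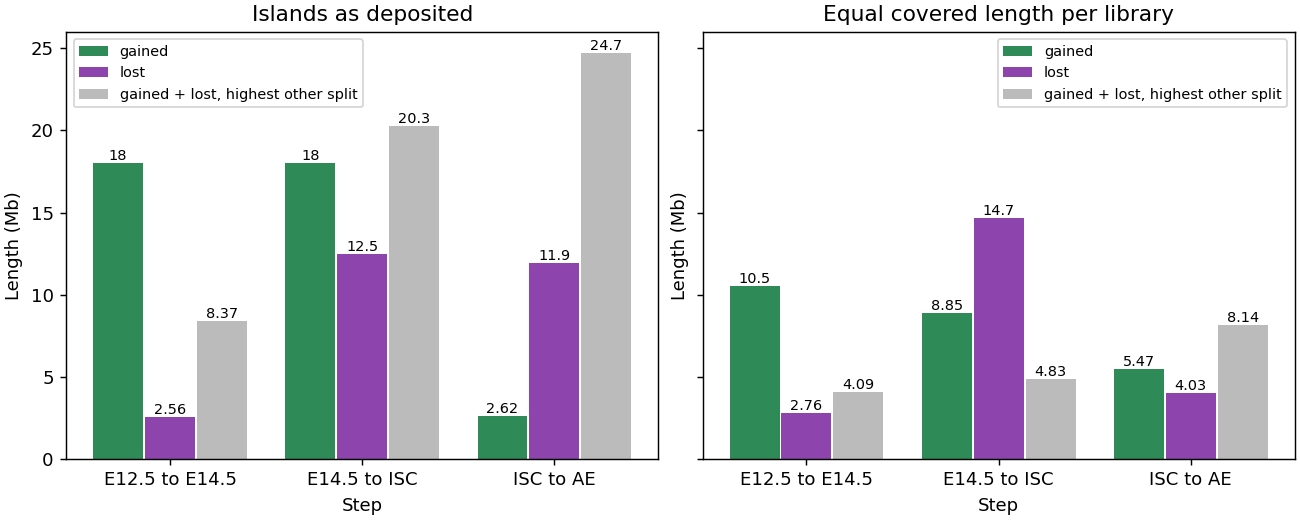
Length in Mb gained (green) and lost (purple) at each step, and the gained plus lost length of the mixed split that gave more (grey), for the islands as deposited (left) and at equal covered length (right). From ISC to AE the mixed split gave 24.7 Mb with the islands as deposited, above the 2.62 Mb gained and 11.9 Mb lost.

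Most of the change lay in unbroken runs, called in both libraries of a group, that held no length covered in all 4 libraries. A gap between islands in a single replicate breaks a run, so such runs need not be separate domains. The 41.2 kb ISC gain on chromosome 7 ended at 52949600, and an ISC replicate 2 island that both E14.5 libraries partly covered began at 52951001. From E12.5 to E14.5, 18.98% of the gained and 12.1% of the lost length shared a run with length covered in all 4 libraries. These shares were 12.4% and 9.69% from E14.5 to ISC, and 14.2% and 16.2% from ISC to AE. Among the 35.9 Mb where the replicates of every group gave the same call, 30.6% was covered in all groups, 18.7% in ISC alone, 15.3% in E14.5 alone, 12.4% in ISC and AE and 3.93% in E12.5 and E14.5.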

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

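The only value that stood apart from its set among 14 sets tested was the covered length of ISC replicate 1, 241.233 Mb against 60.8 to 91.0 Mb in the other 3 adult libraries. Its gap to the nearest of them was 0.833 of the range of the 4 libraries, and chance alone singles out about 1 set in 20. Its ChIP library size relative to the control it shares with replicate 2 was 1.09 times that of replicate 2, and its covered length was 4.72 times that of replicate 2 among islands with a fold of 1.5 or more and 7.28 times with an FDR of 1e-10 or less. The fold of 1.5 was chosen after the result was seen.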

How the results depend on the processing

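The fold of 1.5, equal covered length with 1 replicate left out, the removal of high-input islands and every setting of the X share were chosen after seeing the data. Neither difference in agreement changed sign in any setting run. The higher mean agreement of same-group pairs passed the threshold as deposited, at equal covered length, without X and Y, with a fold of 1.5, without high-input islands and with islands covered by 50% or more in place of the Jaccard index, but not with an FDR of 1e-10 or less (difference 0.0758, exact permutation p = 0.0762). With 1 replicate left out the difference ran from 0.0297 to 0.112, and the call was lost without either E14.5 or either AE library. The embryonic against adult difference was 0.0687 with an FDR of 1e-10 or less and 0.0676 with a fold of 1.5 or more (exact permutation p = 0.0571 for each), and passed in the other settings without a block, each left-out replicate included (0.0669 to 0.0830). The cause of these losses was not tested.

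Replicate numbers did not pair the samples: deviations of same-numbered libraries correlated between -0.0336 and 0.0266 over the 6 pairs of groups, and only 2 numbers exist. With the replicate number as a block the group difference was 0.0773 (exact permutation p = 0.0833, 24 arrangements) and the embryonic against adult difference 0.0595 (exact permutation p = 0.111, the smallest that 9 arrangements allow). For lengths called in both libraries and in neither, the block gives the same values by construction.

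Many lengths moved by over 1.5 times in these settings. Equal covered length changed the gains to 10.5 Mb (E12.5 to E14.5), 8.85 Mb (E14.5 to ISC) and 5.47 Mb (ISC to AE), the ISC to AE loss to 4.03 Mb (so that losses exceeded gains from E14.5 to ISC, and gains exceeded losses from ISC to AE) and the embryonic-alone length to 2.16 Mb. An FDR of 1e-10 or less gave a loss of 0.0618 Mb from E12.5 to E14.5, a gain of 3.29 Mb from E14.5 to ISC, 0.736 Mb gained and 2.24 Mb lost from ISC to AE, and 0.303 Mb embryonic and 1.39 Mb adult alone. A fold of 1.5 or more gave 11.5 Mb gained and 0.370 Mb lost, 5.56 Mb gained, 1.44 Mb gained and 5.41 Mb lost in the same order of steps, and 0.702 and 1.40 Mb alone. The cause of these shifts was not tested. A fold of 3 or more left E12.5 replicate 1 without an island and so gave no value for comparisons that include it. The later steps had 0.00420 Mb gained and 2.46 Mb lost, then 0.0528 Mb gained and 0.00500 Mb lost.

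Leaving out 1 replicate relaxes the rule to a single library, so lengths rose. The relaxation is uneven. With an earlier library left out, a loss needs a call in 1 library and a gain in 2, which favours losses. With a later library left out, it favours gains. Ranges were 21.1 to 57.5 Mb gained and 2.88 to 34.7 Mb lost from E12.5 to E14.5, 19.5 to 165 Mb gained and 13.5 to 37.9 Mb lost from E14.5 to ISC, and 3.15 to 18.96 Mb gained and 17.9 to 149 Mb lost from ISC to AE. The longer direction turned round without E12.5 replicate 1 in the first step (28.3 Mb lost, 21.1 Mb gained), without E14.5 or ISC replicate 1 in the second and without AE replicate 1 in the third, and without E12.5 replicate 2 the first step was nearly balanced. Except without ISC replicate 1, these turns went the way the relaxed rule favours. They therefore do not show that the direction rests on the library left out. Embryonic-alone length ran from 1.49 to 4.80 Mb and adult-alone length from 4.60 to 11.2 Mb, and at equal covered length from 2.30 to 6.39 Mb and from 3.41 to 5.29 Mb. The X share difference ran from 1.32 to 2.16 percentage points, with an exact permutation p of 0.0571 without any 1 of the adult libraries. With a fold of 3 or more its order did not hold. Removing high-input islands, or chromosomes X and Y, moved no length by more than 1.5 times. Promoter windows of other widths, other gene sets and the gene lists were not run, for want of an annotation of the build. Reads outside the islands are not listed, so an uncalled stretch can hold the mark below detection.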

Other observations

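In this part, the count of other splits, equal covered length with 1 library left out and the X share itself were chosen only after the result was seen. Chromosome X carried 0.432% and 1.39% of the covered length at E12.5, 2.95% and 2.89% at E14.5, 0.135% and 0.301% in ISC and 0.286% and 0.271% in AE. Embryonic libraries thus had 1.92 ± 1.22% (SD, n = 4) and adult libraries 0.248 ± 0.0765% (SD, n = 4), higher in 4 of 4 embryonic libraries (exact permutation p = 0.0286, 0.120 after Benjamini-Hochberg adjustment over 21 chromosomes, 5 of which had this smallest p). The test counted replicates of a population as separate units. Unequal extent of calling is argued against for the lists ranked by p-value, since at equal covered length the lowest embryonic share was still 1.26 times the highest adult share. More X DNA in the embryonic inputs was to be read from the control reads per kb of X relative to autosomal islands, whose embryonic mean was 0.584 times the adult mean. That bound was badly chosen, because in 4 of 8 lists 5 islands held over 50% of the X control reads, so this explanation stays open. Among islands with a fold of 3 or more the order did not hold: shares were 2.67%, 3.84% and 2.79% in the 3 embryonic libraries that kept islands, 2.93% and 38.0% in ISC and 1.07% and 12.4% in AE, where ISC replicate 2 kept 5 islands and the AE lists 97 and 71. The adult mice were males and the sex of the embryos is not given in the labels, so a difference in sex, with an inactive X in female embryos, may account for the share and was not tested.

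The stretches called in embryonic or adult libraries alone came to 1.41 and 4.45 Mb. With the islands as deposited, only the real split reached 5.86 Mb (1 of 35, the smallest share this design allows, next 2.92 Mb). Most of the 35 splits part replicates, which favours the real one. The other splits that kept replicates together gave 0.757 Mb (E12.5 with AE) and 0.208 Mb (E12.5 with ISC). Such splits are too few for a test. The real total was reached by 2 of 35 splits, itself included, with an FDR of 1e-10 or less, with a fold of 1.5 or more and without either E14.5 library, and 3 of 35 without E12.5 replicate 2, so chance is not excluded across settings. At equal covered length the real total was 6.88 times the next, which argues against unequal extent of calling as the cause. With 1 library left out at equal covered length it was 1.28 to 2.79 times the next split. Without X and Y the real total was 2.05 times the next. X carried only 0.736% of the embryonic-alone and 0% of the adult-alone length, so removing it could hardly change the total. This argues only against X or Y length making up the stretches, not against other effects of sex. The stricter islands, where another split gave more (4.15 against 1.69 Mb with an FDR of 1e-10 or less), keep open that unequal strength of enrichment between libraries shapes part of it, as do the age, sex and sorting of the cells, which could not be separated here.

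Islands missing from the next population tended to be weak. In all 6 lists of an earlier group, islands with no overlap in either library of the next group had a lower median fold than islands overlapping both, for example 1.51 against 2.03 in E12.5 replicate 2, 1.60 against 2.05 in E14.5 replicate 2 and 1.38 against 1.82 in ISC replicate 1. Read backwards, AE replicate 1 was the exception among the 6 lists of a later group, with 1.49 for islands absent from ISC against 1.45. Part of the losses may therefore be islands near the calling threshold, a candidate explanation that these medians (6 of 6 lists) are consistent with. It does not extend to every region: the losses from E14.5 to ISC on chromosome 3 (14890201 to 14920600) and chromosome 11 (40256001 to 40286000) had E14.5 folds of 2.73 to 3.48, above the median folds of 1.79 and 2.05 of islands kept in ISC.

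Along the series, 21.4% of the length gained from E12.5 to E14.5 was called in both ISC libraries, 43.8% in a single one and 34.8% in neither (19.6%, 28.6% and 51.8% at equal covered length). In AE, 19.1% of it was called in both libraries and 57.7% in neither (19.2% and 57.9% at equal covered length). Of the 12.48 Mb lost from E14.5 to ISC, 50.2% had been called in neither E12.5 library and 13.3% in both (37.2% and 19.8% at equal covered length). At equal covered length the Jaccard index between ISC and AE libraries averaged 0.346 over 4 pairs (0.314 to 0.386), beside 0.338 between the ISC replicates. E12.5 and E14.5 libraries averaged 0.304 (0.212 to 0.398). Embryonic with adult populations averaged from 0.192 (E12.5 and AE) to 0.287 (E14.5 and ISC, pairs of 0.262 to 0.328), and E14.5 and AE libraries 0.272. E14.5 libraries were thus nearly as close to the adult libraries as to the E12.5 libraries on average.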
